A study of Mus musculus with 14 samples.

How the data were processed

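The series measured gene expression by RNA sequencing in 14 samples of mouse colon, 7 after gavage with PBS and 7 after gavage with B. thetaiotaomicron. RNA was column-purified and libraries were made with a SMARTER kit for mRNA, per the labels' protocols. The aligner and the counting program are not given in the sources used here, nor is whether counting used strand. The submitters' processing notes name the builds GRCm38 and mm10. Coordinates in the deposited table differ from those of GENCODE M21 on GRCm38: of 21794 shared gene identifiers, 514 start at the same position. Whether the build, the annotation or the way positions were written differs was not tested. Gene positions in the text were therefore taken from GENCODE M21 by identifier, and the table's coordinates were not used. Of the shared identifiers, 21755 are protein-coding.

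The authors deposited 1 table with raw read counts per gene, per the file headers, for 21898 genes. It also holds FPKM values that the authors computed, per the file headers. These equal the count divided by gene length and by the library's total of counts, so they carry no further information and were not tested. All per-sample columns were matched to samples by library name. The label for treatment and the label for batch are the same in all 14 samples, so groups were taken from the titles, and no value could be recomputed within batches. Replicate numbers come from the library names.

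Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 14070. Counts were scaled by TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F test, robust dispersions, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were the fold change divided by the square root of F. Levels are CPM on TMM-scaled library sizes, and log2 CPM used a prior count of 2. Total counts of 13150140 to 16781708 per sample set the precision, together with a biological coefficient of variation of 0.21. The p-values measure the spread between these samples.

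Before the data were examined, 44 gene lists were fixed (pathways, colonic and neighbouring cell types, blood pressure and clock genes), of which 42 had at least 5 tested members. The pancreatic acinar and anal squamous lists had 4 tested members each and were not tested. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. Counts within a list were adjusted over the list alone and over all genes. A list score is the mean log2 CPM of its members, compared by two-sided exact permutation over 3432 arrangements. This comparison of list scores was added after the data were seen.

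The genes named in the text follow a rule fixed at the same time: the 8 with the smallest p in each direction among those past the threshold with an established symbol and at least 1 CPM in the higher group, up to 3 members of each list past the threshold over all genes, and Fut2, Ang4, Reg3g, Muc2, Agtr1a, Nr3c2, Scnn1a, Slc26a3 and Nr1d1 whatever their result. Some genes that the rule picks are not reported here. Other list members given as examples were chosen after their values were seen.

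The test was checked on simulated counts for all 14070 genes, drawn at the real means, dispersions and library sizes for this comparison. Of 50 genes changed at each size, 34% were recovered at 1.3-fold, 72% at 1.5-fold, 82% at 2-fold and 96% at 3-fold, with 5 false calls among 147. With no gene changed, 0 genes and 0 lists were called. With only the interferon list changed, 3 lists were called, that list among them. Simulated genes vary independently, unlike real ones.

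Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, other scaling factors, other count filters, non-robust dispersions, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a smooth muscle score as covariate, other thresholds, and leaving out each sample. After the data were seen, a distal hindgut score as covariate and a fit without 4 libraries were added. That fit leaves out PBS samples 1, 3 and 5 and B. thetaiotaomicron sample 3, so its groups are smaller and unequal. Counts of genes passing in it can be lower for that reason alone. Figures were drawn with matplotlib 3.10.9.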

Results

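RNA from the colon of wild-type mice was sequenced after oral gavage with phosphate-buffered saline (PBS) or with Bacteroides thetaiotaomicron, a common anaerobic gut bacterium that breaks down dietary and mucosal polysaccharides. The title of the series sets the bacterium in the context of saliva and hypertension, and its design compares the 2 gavages. There were 7 PBS samples and 7 B. thetaiotaomicron samples. Most titles call the samples biological replicates, and the labels do not say whether each came from 1 animal. The total count per sample ranged from 13150140 to 16781708 and did not differ between the groups by a two-sided exact permutation test (p = 0.679, n = 7 each). All pairs of libraries differed by more than sampling noise, so none was counted as a repeat of another. That check cannot show that the samples came from different animals.

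The libraries differed most along an axis shared by both groups. The first principal component held 45.9% of the variance and the second held 14.4%. Hoxb13 and Hoxd13, transcription factor genes that mark the distal hindgut, varied widely within each group: Hoxd13 ranged from 0 CPM (counts scaled to library size) in PBS sample 4 to 216 CPM in PBS sample 3. The mean log2 CPM of the distal hindgut list was 3.49 ± 1.11 (SD, n = 7) with PBS and 3.14 ± 0.62 (SD, n = 7) with the bacterium, which did not differ by a two-sided exact permutation test (p = 0.474). PBS samples 1, 3 and 5 and B. thetaiotaomicron sample 3 lay at the low end of the first component, and PBS sample 4 stood apart on the second.

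**Figure D1:**
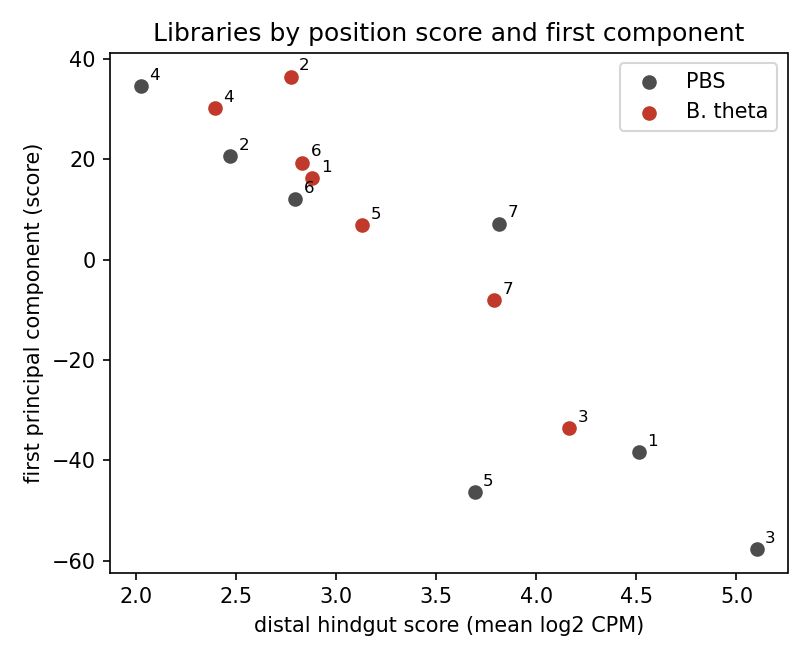
Each point is 1 library, numbered by replicate, with the mean log2 CPM of the distal hindgut list on the x axis and the score on the first principal component on the y axis. Both groups spread along the same diagonal, from PBS sample 4 at a hindgut score of 2.03 to PBS sample 3 at 5.10.

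The comparison asked which colonic genes differed after gavage with the bacterium. Interferon-induced genes led those that were higher. Ifi27l2a, an interferon-induced gene, rose from 12.5 ± 2.73 to 27.2 ± 6.54 CPM (SD, n = 7 each), a log2 fold change of 1.12 ± 0.16 (SE). Ifitm3, which encodes a membrane protein that restricts virus entry, rose from 59.5 ± 8.05 to 97.3 ± 15.4 CPM (SD, n = 7 each), a log2 fold change of 0.71 ± 0.11 (SE). Bst2, which encodes tetherin, rose by 0.88 ± 0.15 (SE) on the log2 scale, and Ifi204, a sensor of foreign DNA, by 1.12 ± 0.19 (SE). Hsh2d, Phf11a, Slfn1, Cytip and Ms4a6b, all expressed in immune cells, rose by 1.15, 2.24, 1.69, 0.42 and 0.58 on the log2 scale. Phf11a, Ifi204, Ifi27l2a, Slfn1 and Ms4a6b have close paralogs, so their values depend on how shared reads were counted.

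Among the genes that were lower, Akr1b7, an aldo-keto reductase gene, had a log2 fold change of -1.55 ± 0.30 (SE), from 1.56 ± 0.59 to 0.53 ± 0.23 CPM (SD, n = 7 each). Mfap4, which encodes a protein of elastic fibres, had a log2 fold change of -0.44 ± 0.08 (SE). Ston1, an endocytic adaptor gene, Usp31, a deubiquitinase gene, and Fam222b, whose function is little known, followed at -0.48, -0.48 and -0.47. Hs6st1, a heparan sulfate sulfotransferase gene, Sec14l1, a lipid-binding protein gene, and Fhod1, a formin gene, had log2 fold changes of -0.36, -0.31 and -0.29.

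Of 14070 genes tested with edgeR's quasi-likelihood test, 35 passed a Benjamini-Hochberg adjusted p of 0.05, 22 higher and 13 lower, and the smallest adjusted p was 0.0378. An unadjusted p under 0.05 was reached by 2145 genes, where 704 would be expected by chance. Of 100 splits of the 14 libraries, the real one included, 5 gave as many, so chance cannot be excluded for that number. The count of calls depended on single libraries: it was 0 without PBS sample 5, 6 or 7 or without B. thetaiotaomicron sample 1, 2, 4 or 6, was 1 without PBS sample 1 or 3, was 2 without B. thetaiotaomicron sample 7, was 8 without B. thetaiotaomicron sample 3, and was 121 without PBS sample 2. Across these 14 fits, 1684 to 2626 genes had an unadjusted p under 0.05, and all 35 genes kept their sign. DESeq2 called 435 genes on the same counts.

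**Figure D2:**
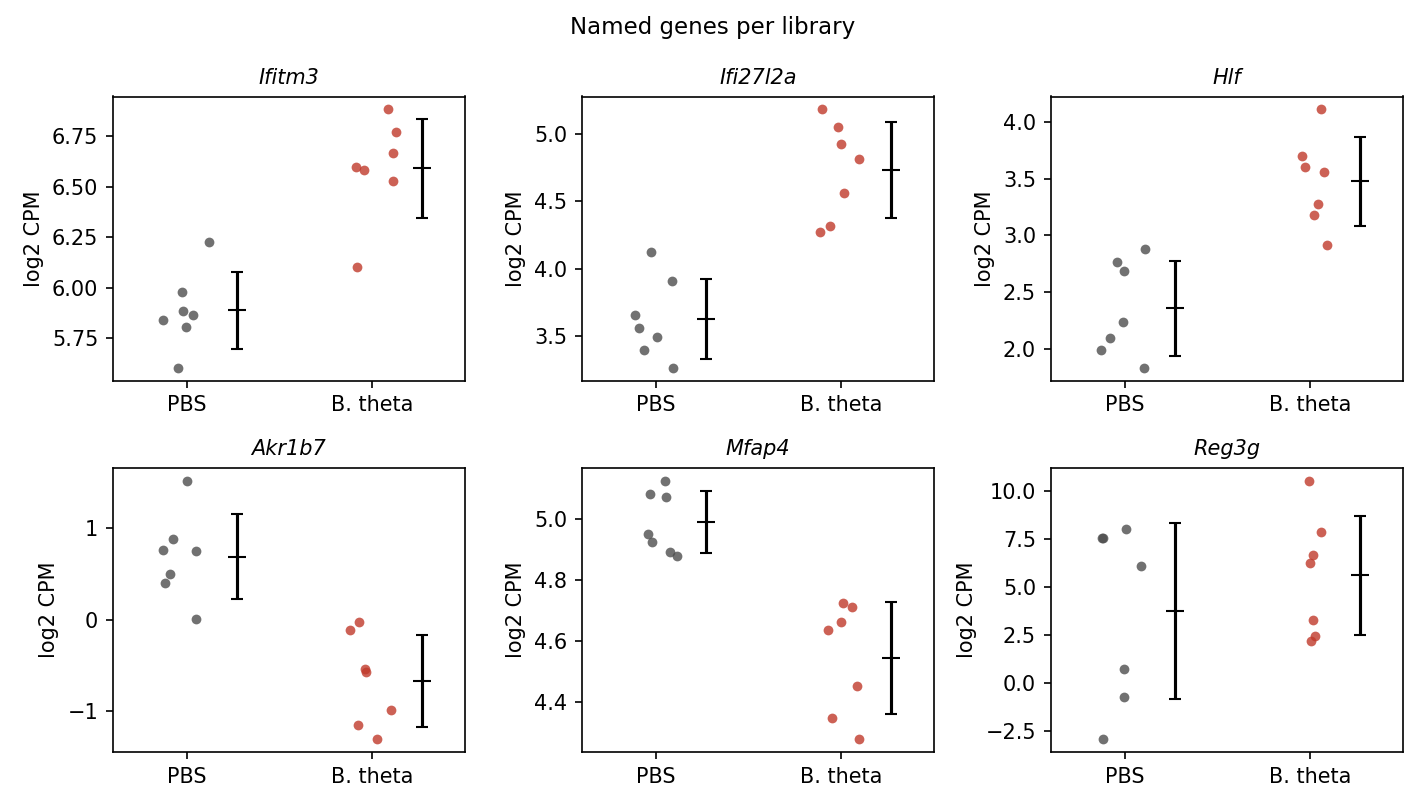
Each panel plots the log2 CPM of 1 gene in each library, with the mean and SD of the 7 samples of a group beside the points. Ifi27l2a, Hlf, Akr1b7 and Mfap4 are fully separated between the groups, while Reg3g spans most of its range in both.

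Ifitm3 (ENSMUSG00000025492) lies on chromosome 7 at 141009586 to 141010770 on the minus strand of GRCm38, and Ifi27l2a (ENSMUSG00000079017) on chromosome 12 at 103442167 to 103443680 on the minus strand. Hlf (ENSMUSG00000003949) lies on chromosome 11 at 90336536 to 90390895 on the minus strand. All are protein-coding genes. Counts covered whole genes, so no exon is singled out.

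The interferon response list, fixed before the data were examined, moved as a whole. All 33 members had higher fitted values after the bacterium, with a median log2 fold change of 0.86 (camera adjusted p = 1.51e-20, and adjusted p = 0.35 with an estimated correlation). Adjusted over the list alone, 29 rose and 4 did not pass, and Bst2 passed over all genes tested. Ifit2 rose from 63.8 ± 36.1 to 234 ± 86.8 CPM (SD, n = 7 each), a log2 fold change of 1.88 ± 0.43 (SE), and Isg15, which encodes a ubiquitin-like modifier, by 1.52 ± 0.42 (SE) on the log2 scale. Usp18, the protease that removes that modifier, rose by 1.40 ± 0.35 (SE), and Oas1a, an RNA sensor with near-identical paralogs, by 0.81 ± 0.18 (SE). The mean log2 CPM of the list was 5.29 ± 0.89 (SD, n = 7) with PBS and 6.39 ± 0.42 (SD, n = 7) with the bacterium. It lay above the PBS median in 7 of 7 samples, with p = 0.00175 by a two-sided exact permutation test and 0.0367 after Benjamini-Hochberg adjustment over the 42 lists. PBS sample 3 had the lowest score, 3.38, and without it the difference was 0.78 rather than 1.10 (exact permutation p = 0.0035).

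Macrophage and dendritic cell genes formed the next group, with a median log2 fold change of 0.33 (adjusted p = 0.35 with an estimated correlation). Of 30 members, 19 rose over the list alone, 3 of them over all genes tested: Cybb, the NADPH oxidase subunit of phagocytes (0.50 ± 0.09, SE, log2 scale), Mpeg1, a pore-forming protein of macrophages (0.51 ± 0.09), and Itgax, which encodes CD11c (0.61 ± 0.11). Lyz2, the myeloid lysozyme, rose from 293 ± 32.1 to 369 ± 44.7 CPM (SD, n = 7 each). The list score rose by 0.30 (exact permutation p = 0.00291, adjusted p = 0.0367). MHC class II genes had a median of 0.36, and 6 of 13 rose over the list alone, among them Ciita, the regulator of the class (0.49 ± 0.15, SE), and H2-Ab1 (0.44 ± 0.14, SE). Their list call was lost, with adjusted p = 0.605 with an estimated correlation. Without the 4 libraries at the low end of the first component, a choice made after seeing the data, 16 interferon genes, 11 macrophage genes and 0 MHC class II genes passed over their lists in edgeR. The medians there were 0.50, 0.26 and 0.31, and camera with the preset correlation still called all of these lists.

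Granulocyte and mast cell genes had low counts and a median log2 fold change of 0.92 (adjusted p = 0.35 with an estimated correlation). Over the list alone, 8 of 17 rose, including Csf3r, the receptor for granulocyte colony-stimulating factor, from 5.68 ± 4.86 to 19.4 ± 9.83 CPM (SD, n = 7 each). S100a9, an abundant neutrophil protein gene, rose by 2.45 ± 0.83 (SE) on the log2 scale from a mean of 0.746 CPM. Plasma cell genes had a median of 0.19 (adjusted p = 0.35 with an estimated correlation), and 4 of 11 rose over the list alone: Prdm1, Jchain, Tnfrsf13b and Derl3. Jchain, which joins polymeric antibodies, went from 1541 ± 237 to 1951 ± 244 CPM (SD, n = 7 each). T and innate lymphoid cell genes (median 0.25) and B cell genes (median -0.43) were called as lists but had no member past the list-alone threshold. Those calls were lost at adjusted p = 0.628 and adjusted p = 0.641 with an estimated correlation. The T cell list was also not called without the 4 libraries (PBS samples 1, 3 and 5 and B. thetaiotaomicron sample 3; adjusted p = 0.85, median 0.05), nor the B cell list with the distal hindgut covariate (adjusted p = 0.0766). Without PBS sample 3, 3 granulocyte genes passed over the list and the T cell median was 0.13. Leaving out 1 library gave B cell medians from -0.66 to -0.21. In the fit without the 4 libraries, 0 granulocyte genes and 1 plasma cell gene passed, with medians of 0.88 and 0.04.

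Cholesterol biosynthesis genes were higher together. Of 25 members, 23 had higher fitted values, the median log2 fold change was 0.31 (adjusted p = 0.35 with an estimated correlation), and 16 rose over the list alone. Fdft1, which encodes squalene synthase, rose by 0.58 ± 0.12 (SE) and Hmgcs1, which encodes a synthase early in the pathway, by 0.47 ± 0.10 (SE) on the log2 scale. The list score rose by 0.31 (exact permutation p = 0.0035, adjusted p = 0.0367). Without the 4 libraries named above, 17 members passed over the list.

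Cell cycle genes also had higher values. All 30 members of the proliferation list had positive fold changes, with a median of 0.41 on the log2 scale (adjusted p = 0.352 with an estimated correlation), and 21 rose over the list alone, among them Top2a (0.51 ± 0.15, SE) and Mki67 (0.37 ± 0.15, SE). Without PBS sample 3, and likewise without the 4 libraries, 0 passed over the list, and the median was 0.38 and 0.22. Its score had an exact permutation p of 0.0175 and an adjusted p of 0.0881.

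**Figure D3:**
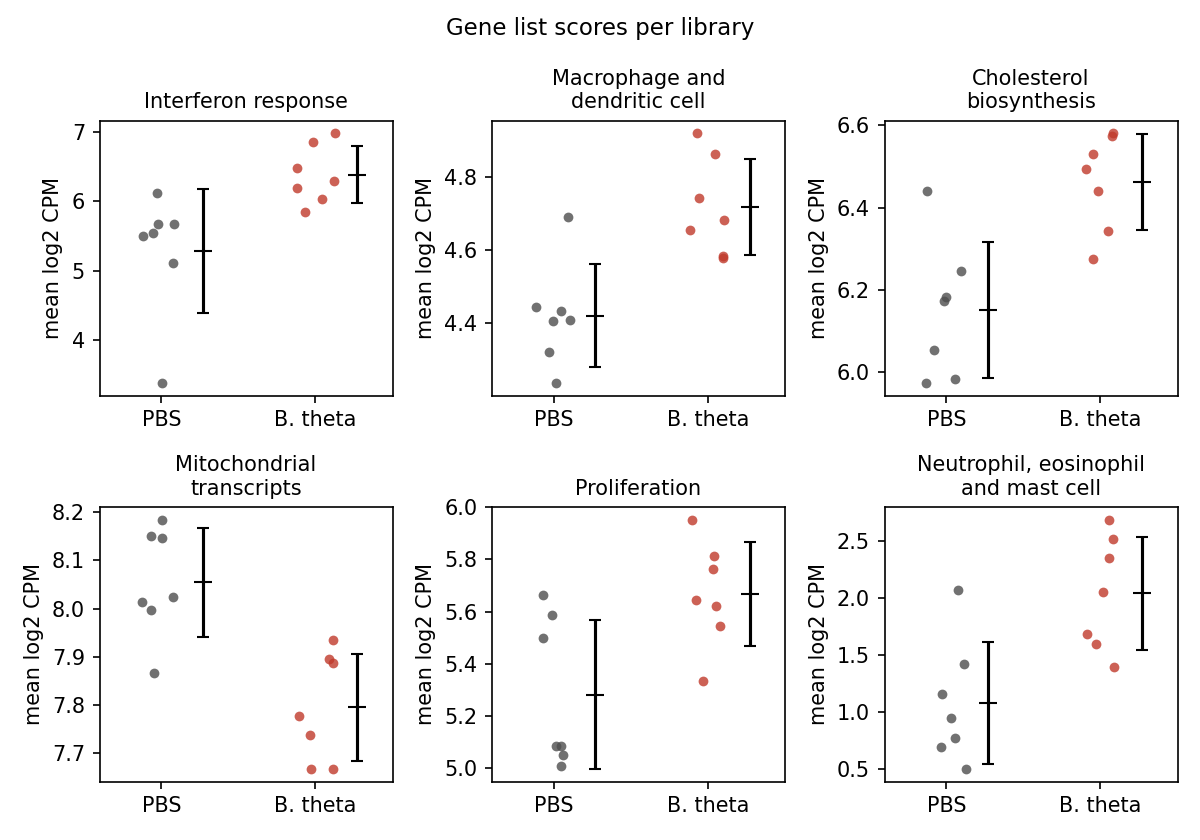
Each panel plots the mean log2 CPM of a gene list in each library, with the mean and SD of the 7 samples of a group beside the points. Mean interferon, macrophage, cholesterol, proliferation and granulocyte scores are higher after the bacterium, mitochondrial transcripts are lower, and single libraries of the groups overlap in each panel. Granulocyte and proliferation scores did not pass exact permutation adjusted over the lists (adjusted p = 0.0636 and 0.0881). PBS sample 3 has the lowest interferon score at 3.38.

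Transcripts of the mitochondrial genome were lower after the bacterium. All 12 had negative fold changes, with a median of -0.23 on the log2 scale (adjusted p = 0.35 with an estimated correlation), and 6 fell over the list alone, among them mt-Nd2 (-0.25 ± 0.06, SE) and mt-Co1 (-0.27 ± 0.07, SE). They took 4.69 ± 0.323% of counts with PBS and 3.98 ± 0.25% with the bacterium (SD, n = 7 each), a difference with an exact permutation p of 0.00233. Their list score had an adjusted p of 0.0367 over the 42 lists. The median was -0.19 and 3 fell over the list without the 4 libraries at the low end of the first component. Nuclear genes of oxidative phosphorylation were not called (median -0.04).

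Matrix and corticosteroid-responsive genes were lower as lists by camera with the preset correlation. Those calls were lost at adjusted p = 0.515 and adjusted p = 0.35 with an estimated correlation. Of 30 fibroblast and matrix genes, 27 had negative fold changes and 6 fell over the list alone, including Eln, which encodes elastin, from 55.0 ± 25.4 to 27.6 ± 2.81 CPM (SD, n = 7 each), and Col4a1 (-0.29 ± 0.07, SE). Among 17 genes of glucocorticoid synthesis and response, Fkbp5, Zbtb16, Sgk1 and Hsd11b2 fell over the list alone and Lcn2 rose. Fkbp5, a chaperone gene induced by glucocorticoids, went from 302 ± 49.1 to 172 ± 54.8 CPM (SD, n = 7 each). Lcn2 is also an antimicrobial gene induced in inflammation. In the fit without PBS samples 1, 3 and 5 and B. thetaiotaomicron sample 3, 0 matrix genes fell over the list and Eln had -0.41. The glucocorticoid list was not called there (adjusted p = 0.0559), with 2 genes lower and Lcn2 at 0.87 without passing. Endothelial genes had a median of -0.11, with Tie1, an endothelial receptor gene, lower over the list alone (adjusted p = 0.628 with an estimated correlation). That list was called by camera with the preset correlation in 15 of 26 other settings. Without PBS sample 3 its median was -0.06 and 0 members passed over it. The inflammatory cytokine list was called higher with a median of 0.02 and no member past the list-alone threshold (adjusted p = 0.515 with an estimated correlation). By camera with the preset correlation it was called in 21 of 26 other settings. With the distal hindgut covariate 1 member passed over it, the neutrophil gene S100a8.

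Clock genes moved in both directions, and the camera test did not call the list (adjusted p = 0.258). Nor did fry for change in 1 direction (adjusted p = 0.431). Fry's test for change in either direction gave an adjusted p of 0.0029, and it called 9 of the 42 lists. Of 20 members, 6 rose and 4 fell over the list alone. Hlf, a transcription factor gene driven by the clock, rose from 5.17 ± 1.52 to 11.4 ± 3.18 CPM (SD, n = 7 each) and passed over all genes tested. Dbp rose by 2.01 ± 0.44 (SE) and Nr1d1, a clock repressor, by 0.85 ± 0.30 (SE) on the log2 scale, though Nr1d1 did not pass over all genes tested (adjusted p = 0.2 by edgeR). Arntl, which encodes BMAL1, had a log2 fold change of -0.59 ± 0.17 (SE), with Npas2, Nfil3 and Clock at -0.44, -0.58 and -0.33. The labels give no time of sampling. Without the 4 libraries at the low end of the first component, 1 member rose and 1 fell over the list, while log2 fold changes were 1.79 for Dbp, 0.997 for Hlf, 0.92 for Nr1d1, -0.70 for Nfil3, -0.43 for Arntl and -0.17 for Clock.

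**Figure D4:**
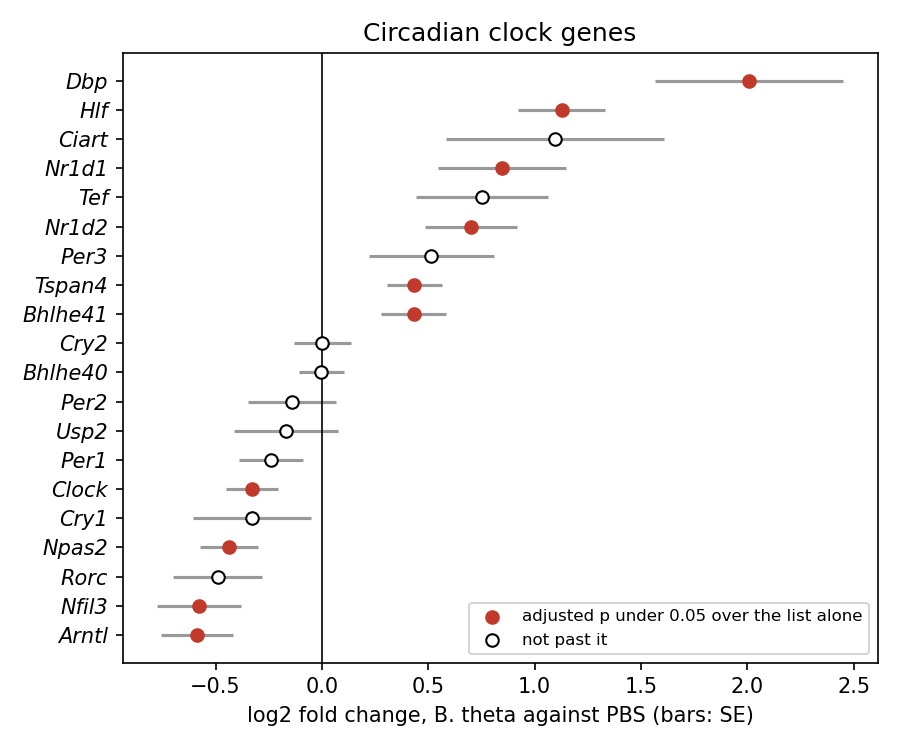
Points are log2 fold changes of the 20 clock genes, B. thetaiotaomicron against PBS, with bars of 1 SE and filled points where the adjusted p over the list was under 0.05. Dbp lies highest at 2.01 and Arntl lowest at -0.59.

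The renin-angiotensin list was not called by camera (adjusted p = 0.258). Agtr1a, the angiotensin receptor gene, had a log2 fold change of -0.52 ± 0.32 (SE) and Nr3c2, the mineralocorticoid receptor gene, of -0.0048 ± 0.13 (SE). Across 27 other settings Agtr1a ranged from -0.84 to -0.11, the latter without PBS sample 4. No member of the sodium, chloride and water transport list passed over the list, though 1 did with the distal hindgut covariate added later, Scnn1b at -0.93 ± 0.22 (SE). Epithelial sodium channel genes had log2 fold changes of -0.25 ± 0.24 (SE) for Scnn1a, -1.20 ± 0.33 (SE) for Scnn1b and -2.59 ± 0.92 (SE) for Scnn1g. Scnn1b and Scnn1g were chosen after their values were seen. Without the 4 libraries at the low end of the first component they had -0.69 and -0.98. Of 31 tested members of the list, 23 had negative fold changes, Sgk1 and Hsd11b2 among them, and 8 had positive ones. Camera did not call the list (adjusted p = 0.275). The chloride exchanger gene Slc26a3 had -0.34 ± 0.47 (SE). Scnn1a ranged from -0.39 to -0.0422 and Slc26a3 from -0.54 to 0.12 across the 27 settings, both lowest without PBS sample 4.

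No member of the antimicrobial and epithelial defence list passed over that list. Lcn2, a member of it as well, passed there with the distal hindgut covariate (0.96 ± 0.26, SE, log2 scale). Reg3g, a bactericidal lectin gene, had a log2 fold change of 1.44 ± 1.5 (SE) and Ang4, an antimicrobial ribonuclease gene, of 0.94 ± 0.998 (SE), and their means of 102 and 45.0 CPM with PBS had SDs of 110 and 80.9 (n = 7 each). Muc2, the main gel-forming mucin, had 0.33 ± 0.43 (SE) and Fut2, a fucosyltransferase of the epithelium, 0.15 ± 0.23 (SE). Single libraries moved these values: Ang4 ranged from 0.50 to 2.56 across the 27 settings, highest without PBS sample 2, and Reg3g from -0.48 to 2.19, lowest without B. thetaiotaomicron sample 2. Muc2 ranged from -0.0626 to 0.47 and Fut2 from -0.0541 to 0.24, the latter highest without PBS sample 2. The 11 tested genes from a list reported after colonisation of germ-free ileum had a median of 0.01 and none passed over the list. That list carried no direction for each gene, so its median cannot tell whether the reported changes recurred.

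Of the 42 lists with at least 5 tested members, camera with a preset correlation called 14, 9 higher and 5 lower. With an estimated correlation 0 remained, 4 having an unadjusted p under 0.05. For change in 1 direction fry called 3: macrophage and dendritic cell, cholesterol biosynthesis and mitochondrial transcripts. For change in either direction it called 9, the clock and interferon lists among them. By exact permutation of list scores, a test added after the data were seen, 4 lists passed an adjusted p of 0.05. The remaining 28 lists, including those of mature colonocytes, goblet cells, stem cells, tight junctions, smooth muscle and enteric neurons, were not called.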

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

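The tests of explanations for the interferon difference were all chosen after the result was seen. Of 150 groups of 7 values examined (list scores, named genes and total counts), 10 held 1 sample far from the other 6, and about 8 would be expected by chance.

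The interferon score of PBS sample 3 was 3.38, below the other PBS samples at 5.12 to 6.12, and its log2 CPM of Hsh2d was 1.15, below 1.87 to 2.37. The higher interferon score after B. thetaiotaomicron did not rest on that library: without it the exact permutation p was 0.003497. It also did not rest on position along the colon as the whole cause, since the difference of 1.10 ± 0.37 (SE) was 0.9656 ± 0.345 (SE) with the distal hindgut score as covariate. Without the 4 libraries at the low end of the first component, PBS sample 3 among them, the median log2 fold change was 0.50 rather than 0.86. A part for position therefore stays open. The difference in score was 0.6276 ± 0.57 (SE) with the macrophage and dendritic cell score as covariate. A change in the number of such cells may therefore account for part of it. That cannot be told apart from induction within cells, because both scores move with the group. An effect of the bacterium stays open as a hypothesis.

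PBS sample 4, which had nearly no Hoxb13 (0.195 CPM), was far below the other PBS samples in the score of sodium, chloride and water transport (7.05), in Slc26a3 (log2 CPM 6.76) and in Scnn1a (6.08). B. thetaiotaomicron sample 3 had a low score for glycosylation of mucins (6.04) and a high score for B cells and germinal centres (3.28). B. thetaiotaomicron sample 2 had a high score for bile acid handling (4.91). PBS sample 2 had a high plasma cell score (5.53). B. thetaiotaomicron sample 5 had a low value of Slfn1 (log2 CPM 1.32).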

How the results depend on the processing

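The 35 genes changed after B. thetaiotaomicron became 435 with DESeq2, 139 with limma-voom and sample weights, 58 with 1 surrogate variable, 71 with the smooth muscle covariate, 198 at an adjusted p of 0.1 and 7 with at least a 2-fold change. Without the 4 libraries at the low end of the first component, chosen after seeing the data, edgeR called 0, with 1481 genes at an unadjusted p under 0.05. Leaving out 1 library gave 0 to 121 genes (0 without PBS sample 5, 6 or 7 or B. thetaiotaomicron sample 1, 2, 4 or 6, and 121 without PBS sample 2). With limma-voom (44), other scaling factors (33 and 33), other filters (27 and 29), non-robust dispersions (39) and the distal hindgut covariate added later (49), the count stayed within 1.5 times. All 35 genes kept their sign wherever they were tested. The median log2 fold change of all genes was -0.01 with each scaling. The causes of these differences were not tested. With the replicate number as a block, edgeR called 15 genes, 10 of them among the 35. Same-numbered samples had correlations from -0.26 to 0.60, 4 of 7 above 0.1, and 2 of 7 PBS libraries correlated best with their own number, so the number was not taken to pair the samples.

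The 14 gene lists changed became 0 with an estimated inter-gene correlation and 3 with fry. Of 364 other list medians of these 14, all under camera with the preset correlation, 341 kept their call. The call was lost by 23 and 0 turned. That test called a median of 10 lists in other splits of the libraries, so a kept call is weak support. Of 593 values for the 22 named genes past the threshold, 312 kept the call, 281 lost it and 0 turned, and adjusted p-values ranged from 4.5e-07 to 0.288. Named genes that had not passed changed sign in 18 of 270 values. With 1 surrogate variable Fut2 had -0.0387, Nr3c2 0.10 and Slc26a3 0.12, and with the distal hindgut covariate Nr3c2 had 0.0692 and Slc26a3 0.0021. Without the 4 libraries Fut2 had -0.0541, Muc2 -0.0626, Nr3c2 0.0933 and Slc26a3 0.10, and with at least 1 CPM in 7 samples Nr3c2 had 0.0033. Leaving out 1 library gave -0.012 to 0.24 for Fut2, -0.48 to 1.89 for Reg3g and -0.0906 to 0.0874 for Nr3c2. The cause was not tested.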

Other observations

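All tests of explanations in this part were chosen after the result was seen, except the counts over other splits of the samples. Families of genes that share a symbol stem, with at least 10 members, were also compared: of 164, camera with a preset correlation called 8 and, with an estimated correlation, 0. Ifi genes (15 of 16 positive), Psmb proteasome subunit genes (9 of 10, median log2 fold change 0.17) and Mcm replication helicase genes (10 of 10, median 0.22) had higher values. Zfp zinc finger genes had lower values in 238 of 346 (median -0.08). Their adjusted p-values with an estimated correlation were 0.592 for Ifi and Psmb and 0.84 for Mcm and Zfp. Among red cell genes, Hba-a1, Hbb-bs and Hbb-bt, which have near-identical copies, fell over the list alone, with Hba-a1 at -1.37 ± 0.46 (SE) on the log2 scale, and 0 passed without PBS sample 3. The heat shock gene Hspa1b had -1.61 ± 0.48 (SE), which did not pass over its list.

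Of the 1716 splits of the 14 libraries into 7 and 7, 100 were drawn. As many genes as the 35 of the real split were called in 2 of the 100, the real one included. That share is under 0.05, but the real count fell to 0 in 7 of 14 fits with a single library left out. For a count this unstable, the share alone does not exclude chance. The highest other count of such genes was 661, from a split with all 4 libraries of the low end of the first component on the same side, which points to a structure of the samples. At an unadjusted p under 0.05, 5 of the 100 gave as many genes as the real 2145, the real one included, with 3326 the highest of the others, so for that count chance cannot be excluded. For gene lists, 27 of the 100 splits called as many as the real 14, with 21 the highest of the others, so chance cannot be excluded for the number of lists.

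The first principal component may follow the position of each piece along the colon. Computed without the list, it correlated with the distal hindgut score at r = -0.9044 (permutation p = 2e-05; Spearman's rho -0.90, p = 2e-05; adjusted p = 6e-05 over 3 relations), and at -0.825 without PBS samples 1 and 3. Within groups r was -0.89 with PBS and -0.953 with the bacterium. Total count had r = -0.06825 (permutation p = 0.815, Spearman's rho -0.08 with p = 0.796). In size this is under the 0.3 that had been set for discounting sequencing depth. Without PBS samples 1 and 7 it was -0.34. A part for depth was left open only after these values were seen, against that limit. The smooth muscle score had r = 0.3604 (p = 0.204; rho 0.14, p = 0.625), and -0.05 without B. thetaiotaomicron sample 3 and PBS sample 5, so the amount of muscle stays open.

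Clock genes moved apart by arm. The first arm held 13 genes, among them Dbp, Hlf and the clock repressor Nr1d1. The second held 6, among them Arntl, Clock and Npas2. A phase score, the mean of the first minus that of the second, was -1.59 ± 0.56 with PBS (SD, n = 7). It was -0.62 ± 0.53 with the bacterium (SD, n = 7), with an exact permutation p of 0.009324. In the first arm 9 of 13 genes were higher, and in the second 6 of 6 were lower. The arms were set after the values were seen, so the p-values of the phase score are not independent support for the shift. The difference of 0.97 ± 0.29 (SE) was 1.034 ± 0.298 (SE) with the distal hindgut score as covariate. The distal hindgut score therefore did not account for it, which covers position along the colon only as far as the score tracks it. The highest exact permutation p with 1 library left out was 0.01923. The arms had been picked on all 14 libraries, so that p cannot exclude a part for a single library. Different times of day of sampling could give this shift and cannot be told apart from an effect of the gavage on the clock, because no sampling times are given in the sources used here.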
